A study of Danio rerio with 4 samples.

How the data were processed

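RNA of adult zebrafish ventricles was sequenced in 4 libraries: WT uninjured, dusp6 mutant uninjured, WT at 20 dpa and dusp6 mutant at 20 dpa, with 1 library per group. Per the labels' protocols, ventricles were flash frozen and RNA was extracted with Trizol and a column kit. The aligner, its version, the genome build and the annotation release are not given in the sources used here. How many ventricles went into each library is also not given. With 1 library per group, no p-value here measures the spread between libraries of a group.

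The authors deposited 2 tables of 31388 genes each, 1 for each 20 dpa library against both uninjured libraries. Per the file headers they hold gene-level expression values, which are whole numbers and were treated as raw counts, and the RPKM that the authors computed from them. The deposited tables also hold the authors' signed fold change (a score in which falls are negative reciprocals) and the p-value and FDR of an EDGE test, per the file headers. The uninjured columns were identical in both tables and were used once, and no column of values per library was left unused as a sample. The authors' RPKM values served only to recover gene model lengths. Gene symbols are those of the tables, and 25925 of the identifiers were found in the gene name table. Names of the form "5 of 6" are the tables' own. pdgfrb could not be matched to a name and no value is given for it.

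Counts were scaled by TMM (edgeR 4.0.16 in R 4.3.3), with factors of 1.06 for WT uninjured, 1.01 for dusp6 uninjured, 0.998 for WT 20 dpa and 0.938 for dusp6 20 dpa. Log2 fold changes were taken from CPM plus a pseudocount of 1, which understates the change of low genes, for genes with at least 50 counts in at least 1 of the libraries compared. Folds given for named genes are ratios of scaled counts without a pseudocount, with exact conditional 95% counting intervals, and a fold against 0 counts is a bound from a floor of 3 counts over the group. Sequencing reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A count of 3 equals 0.0475 to 0.0544 CPM in these libraries.

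Each 20 dpa library was compared with the mean of both uninjured libraries, as in the authors' tables, and with the other 20 dpa library, and the uninjured libraries were compared with each other. In these comparisons the genes past a fold of 2 were counted. Each 20 dpa library was also tested against both uninjured libraries as a group in edgeR, with 1 residual degree of freedom. The residual of this test comes from the difference between the uninjured libraries, which also differ in genotype. The comparisons of 1 library with 1 carry no test. For gene lists, the median log2 fold change was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. This describes these libraries and is not a p-value. The 21 lists, the rule for named genes and most of the alternative settings were set before the data were examined. Named genes were the 8 largest upward and 8 largest downward differences with at least 250 counts in the higher library and a proper symbol, the 3 members of each list with the largest change (of which a subset is printed), and dusp6, nrg1, pdgfrb, vegfaa, nppa, mki67 and pcna. A further 10 lists were written after the data had been seen.

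The additive edgeR quasi-likelihood fit over 4 libraries, with Benjamini-Hochberg adjustment, was also added after the data had been seen. It was tested on simulated data for the injury comparison over 15621 genes, drawn with the same dispersion for every gene. Of 200 changed genes it recovered 13% at 2-fold, 98.5% at 4-fold and 100% at 8-fold, with 0, 8 and 11 false calls. Genes of the data differ in dispersion, so these rates do not carry over to them. For example, the fit did not call pdk2b, 12.1-fold lower in WT and 69.3-fold lower in dusp6 (adjusted p 0.081). The folds, list percentiles and counting intervals were also tested on simulated data. The expectation for shared controls came from 20 simulations with the trended negative binomial dispersion estimated from the uninjured pair. Alternatives were other floors, fold thresholds, pseudocounts and scalings, DESeq2 1.42.0, other uninjured references, left-out gene lists and left-out libraries. RefSeq gene order (assembly GRCz12tu) was used only to find which genes neighbour dusp6, and no coordinates are given because the build of the tables is not given in the sources used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.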

Results

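Messenger RNA of adult zebrafish heart ventricles was profiled by RNA sequencing in 4 libraries, 1 for each combination of genotype and state. Wild-type (WT) fish of the AB* strain and fish homozygous for the pt30a allele of dusp6 were sampled uninjured or 20 days post amputation (dpa), after part of the ventricle had been resected. Dusp6 is a phosphatase that removes activating phosphates from the kinase ERK, and its gene is itself induced by FGF signalling. The total counts were 63222206 in WT uninjured, 60772311 in dusp6 uninjured, 55197408 in WT 20 dpa and 55717125 in dusp6 20 dpa. Mitochondrially encoded genes took between 17.7% and 18.7% of the counts. With 1 library per group no difference between groups had a replicate check, and intervals given for folds are 95% counting intervals that cover counting error only. The column headers named the uninjured pair and the 20 dpa pair by different patterns. The labels gave no batch, so injury and any difference in library preparation cannot be told apart, while genotype was balanced across both patterns. Any difference in genetic background between the WT and the mutant fish would follow genotype and cannot be told apart from it.

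The mutated gene was examined first. The dusp6 transcript (ENSDARG00000070914) was measured at 85.0 CPM (counts scaled by library size and TMM) in WT uninjured, 183 in dusp6 uninjured, 105 in WT 20 dpa and 121 in dusp6 20 dpa. It was thus not lower in the mutant libraries, and its level does not check the labels, since the labels do not say that the allele removes the transcript. The list of FGF and MAPK feedback and target genes, which includes dusp6, had median log2 fold changes of 0.07 in WT and 0.17 in dusp6 against uninjured and 0.05 between the 20 dpa libraries, all inside the central 95% of random lists. It lay above this range between the uninjured libraries (0.24, higher in dusp6, percentile 99.95), where a pseudocount of 10 CPM gave 0.112. It also lay above the range in WT against its own uninjured library (0.26, percentile 99.52). Total-count scaling gave -0.032 between the 20 dpa libraries.

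The first comparison asked which transcripts differed in WT ventricles at 20 dpa from uninjured ventricles, taken as the mean of both uninjured libraries. Several transcripts of DNA replication, of matrix assembly, of macrophages and of the epicardium were higher after resection. The replication helicase genes mcm2, mcm4 and mcm6 were 5.28-fold (interval 4.65 to 6.00), 4.85-fold and 4.70-fold higher, and pcna, which encodes the DNA polymerase clamp, was 2.24-fold higher, while mcm7, of the same helicase, was lower (8.01 CPM against 18.2 and 26.0 in the uninjured libraries). The collagen chaperone gene serpinh1b was 5.96-fold higher (5.50 to 6.46) and the collagen genes col12a1b and col12a1a were 5.04-fold and 3.09-fold higher. The macrophage gene mfap4 was 8.95-fold higher (7.67 to 10.5) and the progranulin gene grn1 was 5.71-fold higher. The uninjured libraries differed for some of these, with 7.47 CPM in WT and 19.5 in dusp6 for grn1, 1.14 and 3.05 for col12a1b and 8.93 and 3.93 for serpinh1b, so these folds depend on the uninjured library taken. The retinoic acid synthesis gene aldh1a2, expressed in epicardium and endocardium after injury, was measured at 150 CPM against 42.3 and 32.3 in the uninjured libraries.

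In total 968 of 15457 genes differed at least 2-fold in WT, 518 higher and 450 lower. Total-count scaling turned the balance to 470 higher and 512 lower, and the WT uninjured library alone gave 547 and 335. Among the 8 largest upward differences with a proper symbol, MYH2 (8 of 8), mylpfa, pvalb4, tnni1d, actc1b and pvalb1 encode sarcomere or calcium-buffering proteins of skeletal muscle. The list of other muscle, liver and gonad transcripts had a median log2 fold change of 1.77 (percentile 100) over 12 members above the floor. With no floor it was 0.480. Members pass the floor by their highest library, so part of the 1.77 is set by the floor. MYH2 (8 of 8) was at 31.3 CPM against 0.13 and 0.72 in the uninjured libraries. The other 2 were fkbp5, a glucocorticoid-responsive chaperone gene, 15.8-fold higher at 143 CPM, and arg2, which encodes an arginase, 10.4-fold higher. arg2 was at 12.8 CPM in WT uninjured and 3.93 in dusp6 uninjured, so its folds at 20 dpa depend on the uninjured library taken. The largest downward differences were nr1d4b, a Rev-erb family clock gene, 33.7-fold lower, akap6, an anchoring protein gene of cardiomyocytes, 19.8-fold lower, pdk2b, a pyruvate dehydrogenase kinase gene, 12.1-fold lower, and fbxo25, 16.4-fold lower. The other 4 were decided by a single uninjured library. apoea, apoa1a and chia.3 were at 30.3, 47.4 and 19.1 CPM in dusp6 uninjured and at 1.07 CPM or less elsewhere, and f13a1a.1 was at 23.6 CPM in WT uninjured and at 0.29 CPM or less elsewhere. Among the downward differences 2 identifiers without a proper symbol were passed over.

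Of the 21 gene lists fixed before the data were examined, 11 had a WT median above the central 95% of 10000 expression-matched random lists and none lay below. The macrophage list had a median of 0.78 (percentile 100), with 9 of 24 members at least 2-fold higher. The extracellular matrix and fibrosis list had 0.57 (percentile 100), with 9 of 40 members 2-fold higher, the epicardium list 0.57 (percentile 100) and the neutrophil list 0.60 (percentile 99.9), with none of its 9 members 2-fold higher and a median of -0.035 at a floor of 250 counts. The immediate early and heat shock list had 0.45 (percentile 100), led by hsp90aa1.1 at 8.33-fold and hspa5, the main chaperone of the endoplasmic reticulum, at 3.29-fold. This list was fixed as a list on RNA handling, and its shift cannot be assigned to resection or to handling here. Smaller shifts were found for the red blood cell list (0.38) and the list of fetal and stress genes of cardiomyocytes (0.32, led by acta1a at 3.22-fold). Glycolysis had 0.28, led by hk2 at 7.76-fold, and oxidative phosphorylation and the TCA cycle had 0.23. Cell cycle and mitosis had 0.21, with 6 of 28 members 2-fold higher and 1, mcm7, 2-fold lower. Its median was 0.041 with a pseudocount of 10 CPM and 0.625 at a floor of 250 counts. This pseudocount gave 0.42 for macrophages and 0.25 for immediate early and heat shock genes. The medians of lymphocytes (0.17), thrombocytes (0.29), mural cells and smooth muscle (0.22), growth factors and receptors (0.15), endothelium and endocardium (-0.04), sarcomere and calcium handling (0.07), fatty acid oxidation (-0.09), mitochondrially encoded genes (0.07) and the interferon response (-0.09) lay inside the range. Against the WT uninjured library alone the medians of red blood cells (0.11), fetal and stress genes (0.26), glycolysis (0.25) and oxidative phosphorylation (0.20) lay inside the range and that of the FGF and MAPK list above it. Among genes of set interest, nrg1, a growth factor for cardiomyocytes, was at 0.59 CPM or less in all 4 libraries, vegfaa differed by -0.13 on the log2 scale, nppa, the atrial natriuretic peptide gene, by -0.02, and mki67 by 0.43. With the genes of gut, pancreas, liver and skeletal muscle lists left out, which were written after the data had been seen, 916 genes differed at least 2-fold. An edgeR quasi-likelihood test with both uninjured libraries as a group called 0 genes at an adjusted p of 0.05, with 2729 of 15457 at an unadjusted p under 0.05.

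**Figure D1:**
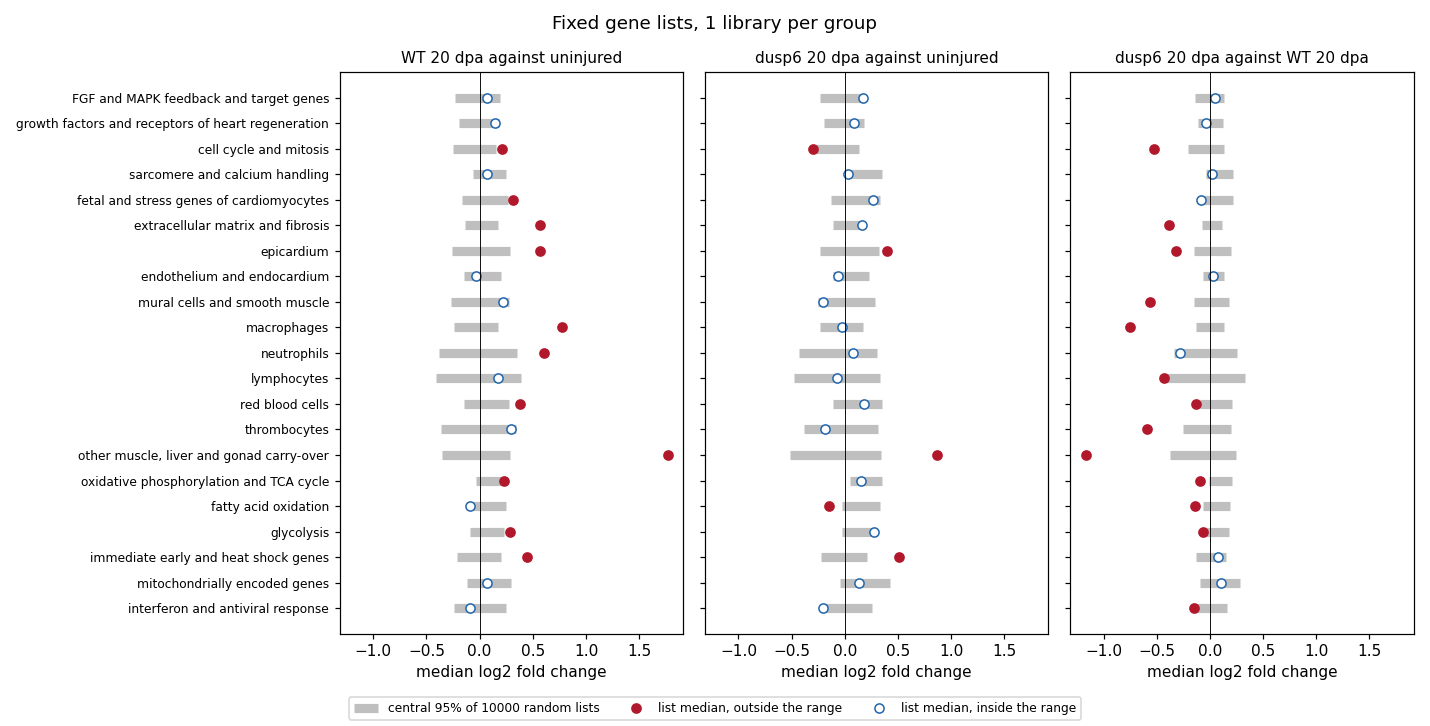
Median log2 fold change of each of the 21 fixed gene lists (points) in 3 comparisons, with the central 95% of 10000 random lists matched on expression (grey bars). The macrophage median was 0.78 in WT, -0.03 in dusp6 and -0.75 between the 20 dpa libraries.

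The second comparison asked the same of the dusp6 ventricles. The medians of the immediate early and heat shock list (on RNA handling) and of the epicardium list were higher than in uninjured ventricles. The macrophage and matrix lists lay inside the range of random lists. hsp90aa1.1 was 8.33-fold higher (interval 7.92 to 8.78, n = 1), hsp70l 6.39-fold, serpinh1b 5.50-fold and aldh1a2 3.10-fold. Of these, hsp70l was at 2.72 CPM in WT uninjured and 1.26 in dusp6 uninjured, and the fold of hsp70l and of serpinh1b was larger against dusp6 uninjured alone. The epicardial transcription factor gene tcf21 was 2.18-fold higher, while clu, also of the epicardium list, was 2.16-fold lower, and 10 of 13 members of this list were above 0. Of muscle genes, tcap, which encodes the titin cap, was 4.04-fold higher and myh6, the atrial myosin heavy chain gene, 3.66-fold higher. Both were also higher in WT 20 dpa, 2.75-fold and 2.12-fold. The ventricular myosin gene vmhc was 2.14-fold lower, at 248 CPM against 356 in WT uninjured and 722 in dusp6 uninjured. Its fold thus depends on the uninjured library taken. The flow-responsive endothelial genes klf2b and klf2a were 4.21-fold and 3.45-fold higher, and 2.63-fold and 2.57-fold higher in WT 20 dpa. Of these, klf2a is also a member of the immediate early and heat shock list.

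At least 2-fold differences were found for 969 of 15408 genes, 471 higher and 498 lower. Total-count scaling gave 354 higher and 680 lower, and this scaling shifted the median of all genes by -0.12 on the log2 scale in the dusp6 comparison. The largest upward differences were calb1, a calcium-binding protein gene with 0 counts in both uninjured libraries and 15.6 CPM in dusp6 20 dpa (at least 666-fold higher, from a floor of 3 counts over both uninjured libraries, with a lower counting limit of 540), lin7b (68.6-fold), clec19a (13.2-fold), hsp90aa1.1, igfbp6b, a binding protein of insulin-like growth factors (7.86-fold), alpk2 (9.27-fold), arg2 (7.65-fold) and zdhhc2 (10.3-fold). 6 identifiers without a proper symbol were passed over among these, and 1 among the following. The largest downward differences were pdk2b (69.3-fold lower), nr1d4b (53.7-fold lower), ACTC1 (5 of 6) and 5 genes decided by a single uninjured library, apoa1a, apoea, chia.3, tcnl and f13a1a.1. ACTC1 (5 of 6), a cardiac actin gene, was at 838 CPM in WT uninjured, 31.4 in dusp6 uninjured, 1541 in WT 20 dpa and 46.8 in dusp6 20 dpa, so this difference followed genotype and not injury. Another gene of this name, ACTC1 (4 of 6), was at 138, 33.5, 537 and 177 CPM in the same order.

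Of the fixed lists, 3 had a dusp6 median above the random range and 2 below. Above were the immediate early and heat shock list (0.51, percentile 100), the epicardium list (0.40, percentile 99.4) and the list of other muscle, liver and gonad transcripts (0.86, percentile 100), which rested on 7 members and was 0.040 with no floor, 0.143 with a pseudocount of 10 CPM and 2.25 at a floor of 250 counts. Below were fatty acid oxidation (-0.15, percentile 0.07), with mlycd, a malonyl-CoA decarboxylase gene, 4.62-fold lower and cpt1b 2.02-fold lower, and cell cycle and mitosis (-0.30, percentile 1.43), with mcm7 3.08-fold and plk1 4.77-fold lower but mcm5 2.66-fold higher. Of the cell cycle members 9 were above 0 and 18 were not. Among the former were mcm2, mcm4 and mcm6, at 5.80, 6.14 and 6.41 CPM against 2.38 to 3.08 in the uninjured libraries. These genes were thus higher at 20 dpa in both genotypes. The median of the cell cycle list was 0.23 among members with at least 250 counts. The macrophage median was -0.03 and the matrix median 0.16, inside the range, although mfap4 (4.14-fold) and grn1 (3.08-fold) were higher. Also inside were growth factors (0.09), sarcomere (0.03), fetal and stress genes (0.26), endothelium (-0.07), mural cells (-0.21, with the elastin genes elnb and elna 6.14-fold and 2.56-fold lower), neutrophils (0.08), lymphocytes (-0.07), red blood cells (0.18), thrombocytes (-0.18), oxidative phosphorylation (0.15), glycolysis (0.28), mitochondrially encoded genes (0.13) and the interferon response (-0.20). Against the dusp6 uninjured library alone, red blood cells (0.56) and glycolysis (0.33) lay above the range and sarcomere (-0.018) below it, so the red blood cell medians of the genotypes stood in the opposite order to that against both uninjured libraries. nppa differed by 0.71, vegfaa by 0.14, mki67 by 0.21 and pcna by 0.57 on the log2 scale. With the gut, pancreas, liver and skeletal muscle lists left out, 945 genes differed at least 2-fold. The edgeR quasi-likelihood test with both uninjured libraries as a group called 0 genes at an adjusted p of 0.05, with 2739 of 15408 at an unadjusted p under 0.05.

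The responses of both genotypes were then set side by side. The immediate early and heat shock list, the epicardium list and the list of other muscle, liver and gonad transcripts lay above the random range in both. Across 15621 genes the log2 fold changes had a Pearson's r of 0.71, and genes are not independent replicates. Since both responses used the same uninjured libraries, simulated libraries with no effect gave 0.34. The covariance was 0.206 against 0.0496 simulated. Against each genotype's own uninjured library, with no library shared, r was 0.55 against 0.001 simulated. Any difference in library preparation between the uninjured libraries and those after resection would still be common to both responses. The simulations did not include such a difference, so the agreement of the responses cannot tell it apart from injury. In all 215 genes were at least 2-fold higher in both and 220 at least 2-fold lower in both, where independent lists of these sizes would share 15.6 and 14.3, and 3 differed 2-fold in opposite directions. Simulated libraries with shared controls and no effect gave 16.5 genes 2-fold different the same way in both, against 435 observed. The simulations drew each gene at the dispersion trend. Genes that vary more than this, such as those decided by a single uninjured library, are therefore under-represented, and 16.5 may be too low. Against each genotype's own uninjured library 355 genes differed the same way in both, 202 higher and 153 lower. Part of the excess with shared controls may come from these controls.

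**Figure D2:**
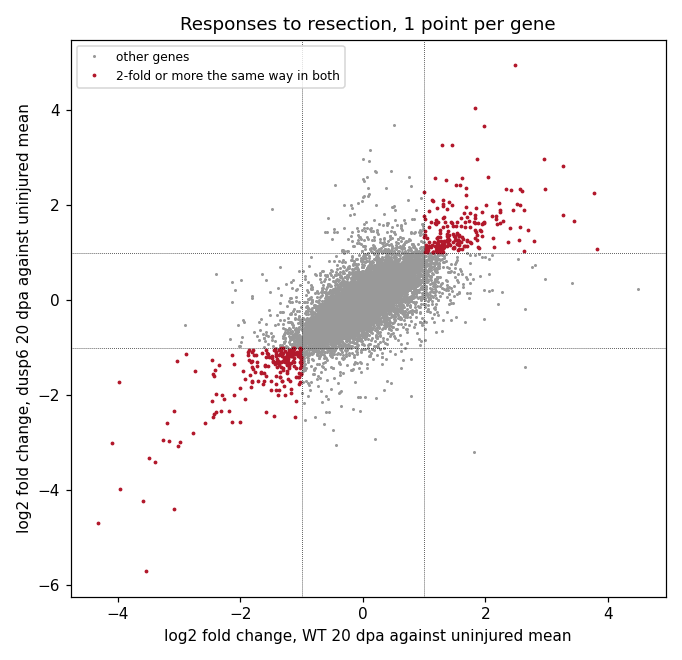
Log2 fold change against the uninjured mean in WT 20 dpa (x axis) and dusp6 20 dpa (y axis), 1 point per gene, with 2-fold limits dotted. The 435 genes at least 2-fold different the same way in both are red.

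An edgeR quasi-likelihood fit over all 4 libraries, with genotype and injury as additive terms and 1 residual degree of freedom, was added after the data had been seen. This fit takes its residual from how far the injury differences of the genotypes part, and not from libraries of the same group. It called 128 of 15621 genes for injury at an adjusted p of 0.05, of which 84 rose and 44 fell, with 4283 at an unadjusted p under 0.05. Among those that rose were the chaperone genes hsp90aa1.1 (12 and 17.6 CPM uninjured, 122 and 122 at 20 dpa), hspa5, manf, sdf2l1 and hspa4a, the tubulin genes tuba8l3, tubb2b and tubb4b, the actin gene actb1, aldh1a2, hk2, klf2b, the alpha globin gene hbaa1 and the parvalbumin genes pvalb1, pvalb2 and pvalb4. Among those that fell were the clock genes nr1d4a, nr1d4b, clocka_1, dbpb and nfil3-5, GABARAPL1, which takes part in autophagy, calcoco1a, angptl4, an inhibitor of lipoprotein lipase, and cat, which encodes catalase. These examples were chosen after their values were seen. Of the fixed lists, members rose in other muscle, liver and gonad transcripts (3 of 13), red blood cells (2 of 16), immediate early and heat shock genes (2 of 23), epicardium (1 of 13), macrophages (1 of 24), endothelium (1 of 29) and glycolysis (1 of 30), and none fell. Adjusted over the list alone, 8, 4, 8, 5, 2, 8 and 3 members of these lists rose, and 3 of endothelium fell. In the cell cycle list none passed over all genes, while adjusted over the list alone 6 rose and 1 fell. The count rests on the settings: most adjusted p-values lay close to the threshold (median 0.0484). Total-count scaling called 1 gene, a floor of 250 counts called 0, a fit without the genotype term called 0 and DESeq2 called 1394. Runs that left out a single library also dropped the genotype term, so they cannot show what that library alone changed. chia.1 and chia.3 were called although they had counts in dusp6 uninjured and at most 1 count elsewhere.

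The authors' deposited table, from a test of each 20 dpa library against both uninjured libraries, listed 480 genes at an FDR under 0.05 for WT (324 higher) and 440 for dusp6 (290 higher). In the authors' deposited table the number passing in both was 190, 131 higher and 59 lower, and 98 of these were also among the 128 genes called for injury.

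The genotype comparison asked how the dusp6 ventricle at 20 dpa differed from the WT ventricle at 20 dpa. The medians of the macrophage, matrix, mural, thrombocyte and cell cycle lists were lower in dusp6, while the median of the endothelium list lay near 0. In the additive edgeR fit, which takes the genotype difference as equal in both states, no member of these lists was called for genotype over all genes, and adjusted over the list alone 3 of 13 mural genes and none of the others were called. The macrophage genes ctssb.1, mpeg1.1 and coro1a were 2.67-fold, 2.54-fold (dusp6 over WT 0.394, interval 0.344 to 0.451) and 2.24-fold lower. The fibronectin gene fn1a and the lysyl oxidase gene loxl2b were 2.65-fold and 2.78-fold lower. The replication genes rrm2_1 and mcm2 were 3.32-fold and 2.5-fold lower, while rrm2_2, of the same name, was 19.6-fold higher (6.39 against 0.33 CPM). Beside these, the list of other muscle, liver and gonad transcripts was lower, with a median of -1.17 (percentile 0.00) that was -0.364 with no floor. Its members apoa2 and tnnt3b were 12.9-fold and 4.80-fold lower.

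At least 2-fold differences were found for 505 of 14790 genes, 220 higher and 285 lower in dusp6, and for 477 with the gut, pancreas, liver and skeletal muscle lists left out. The uninjured libraries differed at least 2-fold in 508 of 15132 genes, so the number at 20 dpa was not larger than without injury. The 8 largest upward differences were myom3, an M-band protein gene (58.1 against 4.59 CPM), scube3, alpk2 (36.9 against 4.36), sypb, tdrd12, rrm2_2, the muscle creatine kinase gene ckmb (163 against 29.8) and the complement gene C7 (2 of 2). The 8 largest downward differences were ACTC1 (5 of 6), 32.9-fold lower, MYH2 (8 of 8), SLA (2 of 2), emilin2b, an extracellular matrix gene (0.36 against 10.7 CPM), tnni1d, fkbp5 (20.6 against 143), the triglyceride synthesis gene dgat2 and the leukocyte integrin gene ITGAL (4.57 against 26.3). 7 identifiers without a proper symbol were passed over among the upward and 4 among the downward differences.

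Of the fixed lists 13 had a median below the random range and none above. The macrophage list had -0.75 (percentile 0.00), with 8 of 24 members at least 2-fold lower and 1 member above 0. Thrombocytes had -0.59, mural cells and smooth muscle -0.57, cell cycle and mitosis -0.53, extracellular matrix and fibrosis -0.39 and epicardium -0.32. Of 32 cell cycle genes matched, 25 were above the floor and none of these was above 0. This list counted rrm2_1 and not rrm2_2, which was higher in dusp6. The lymphocyte median of -0.43 rested on 5 members and was -0.048 with no floor and -0.105 with a pseudocount of 10 CPM. This pseudocount also gave smaller medians for macrophages (-0.435), thrombocytes (-0.236), cell cycle (-0.096, and -0.344 with no floor), matrix (-0.279), mural cells (-0.456) and epicardium (-0.146). Shifts of 0.15 or less in size were found for the interferon response (-0.15), fatty acid oxidation (-0.14), red blood cells (-0.13), oxidative phosphorylation (-0.09) and glycolysis, whose median was -0.06 and whose mean was 0.015. The medians of endothelium (0.03), sarcomere (0.02), growth factors (-0.04), neutrophils (-0.29), fetal and stress genes (-0.08), immediate early and heat shock genes (0.07) and mitochondrially encoded genes (0.11) lay inside the range. Within the sarcomere list vmhc and actn2b were 2.71-fold and 2.07-fold lower, while myh6 was higher (250 against 145 CPM). nppa, of the fetal and stress list, was 1.66-fold higher. pcna differed by -0.56, mki67 by -0.22 and vegfaa by 0.27 on the log2 scale. The difference between the responses of the genotypes, each against its own uninjured library, was at least 2-fold for 941 genes, and no test of it could be made with 1 library per group.

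In the uninjured ventricles, dusp6 differed from WT at least 2-fold in 508 genes, 277 higher and 231 lower, and total-count scaling turned the balance to 250 higher and 264 lower. The apolipoprotein gene apoa1a (47.4 against 0.27 CPM) and the chitinase gene chia.3 (19.1 CPM against 0 counts) were higher in the dusp6 library. Red blood cell transcripts were lower, with a median of -0.35 (percentile 0.00) and 0 of 16 members above 0. Glycolysis had -0.23 and mural cells -0.29, while the FGF and MAPK list had 0.24, the matrix list 0.14 and the cell cycle list 0.18, each outside the random range. With a pseudocount of 10 CPM the FGF and MAPK median was 0.112 and the cell cycle median 0.046. At a floor of 250 counts the cell cycle median was 0.492. The matrix list had 3 members 2-fold lower and 1 higher, and its value was 0.042 to 0.073 with means, no floor, a floor of 250 counts, a pseudocount of 10 CPM or total-count scaling. Between the states, 77 genes differed between genotypes at least 2-fold the same way uninjured and at 20 dpa, 33 higher and 44 lower in dusp6. In the additive edgeR fit 1 gene fell with the mutant genotype, ACTC1 (5 of 6) (ENSDARG00000076126), at an adjusted p of 0.0292, lower in both pairs of libraries, and a floor of 250 counts gave 0 genes. In this fit 1380 genes had an unadjusted p under 0.05. DESeq2 called 149 genes, and edgeR without the injury term called 0. emilin2b came next (adjusted p 0.0997 in edgeR), at 17.8 and 10.7 CPM in WT against 0.77 and 0.36 in dusp6.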

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

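No difference between the genotypes at 20 dpa alone could be tested, since each group had 1 library, and the tests of the macrophage list against the endothelium list and against the uninjured pair were chosen after the result was seen. bgnb, the biglycan gene, moved in opposite directions in the genotypes, each against its own uninjured library. Its log2 fold change was -1.14 in WT and 1.35 in dusp6, a difference of 2.49, with 6.78 and 2.52 CPM in WT and 2.33 and 7.48 CPM in dusp6. mhc1uba, a class I histocompatibility gene, had 1.75 in WT and -1.12 in dusp6, a difference of -2.87, with 75.5 and 256 CPM in WT and 209 and 95.8 CPM in dusp6. The cell cycle and mitosis list had a median of 0.34 in WT and -0.39 in dusp6, a difference of -0.72, and its dusp6 median against both uninjured libraries was 0.23 at a floor of 250 counts.

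The cell cycle difference belongs to a wider pattern, in which macrophage, matrix and cell cycle lists were lower in dusp6 20 dpa than in WT 20 dpa. With a pseudocount of 10 CPM the macrophage median was -0.435 and that of cell cycle -0.096. The additive edgeR fit, which takes the genotype difference as equal in both states, called no member of these lists for genotype. Scaling as the source is argued against, since under 3 other scalings the macrophage median was -0.746 or lower, against -0.748. A lower share of every cell type other than cardiomyocytes would lower endothelial and macrophage genes alike. The macrophage median lay 0.777 below that of endothelium (-0.777, random pairs of lists -0.191 to 0.137). However, the medians of thrombocytes (-0.589), mural cells (-0.568), lymphocytes (-0.434), epicardium (-0.323), neutrophils (-0.286) and red blood cells (-0.129) were also below 0, with sarcomere at 0.020. The comparison with endothelium thus does not speak to a lower share of these cell types without endothelium. The macrophage difference of -0.748 also lay outside the range around the value of the uninjured pair (-0.005 to 0.257), although 1 pair cannot show how far hearts of 1 genotype differ. Transcripts of other organs moved the same way between these libraries. Their medians were -1.17 for other muscle, liver and gonad transcripts, -1.20 for exocrine pancreas, -0.92 for liver and -0.54 for fast skeletal muscle. The last 3 of these lists were written after the data had been seen. Many members of the first 3 lists reached the floor only in WT 20 dpa, so these sizes are partly set by the floor. With no floor the first median was -0.364. What stays open is a difference between individual hearts or in the extent of the wound, an effect of the genotype, the fraction of wound tissue in each sample and neighbouring tissue in the WT 20 dpa library, none of which can be told apart with 1 library per group.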

How the results depend on the processing

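No paired analysis was possible by replicate number, because each group has a single library, and the additive fit takes genotype as a term. The total-count scaling of lists, own-genotype references for lists, left-out carry-over lists (gut, pancreas, liver and skeletal muscle), other-genotype references, the difference of own-genotype responses and all settings of the additive fit were chosen after the data had been seen. The cause of the shifts below was not tested unless stated. Floors of 5 counts and none gave 968, 969, 505 and 508 genes, as in the results, because a gene under 50 counts cannot reach 2-fold over the pseudocount. Median-ratio and total-count scaling, left-out red blood cell and mitochondrial genes, left-out carry-over lists and either uninjured library alone gave 2-fold counts within 1.5 times of these. In the order WT, dusp6, between the 20 dpa libraries and between the uninjured libraries, a fold of 1.5 gave 3183, 3199, 1621 and 1593 genes, a fold of 4 gave 98, 110, 64 and 76, and a pseudocount of 10 gave 201, 166, 64 and 75. A floor of 250 gave 303 between the 20 dpa libraries, and the difference of own-genotype responses gave 941. Genes also at an FDR of 0.05 in the authors' deposited table were 441 in WT and 402 in dusp6. edgeR with the uninjured libraries as a group gave 0 in each (2729 and 2739 at an unadjusted p under 0.05). No call by the authors' FDR exists for the genotype comparisons. The agreement of the responses was 0.547 against own uninjured libraries and 0.746 at a floor of 250, while Spearman's rho was 0.715. A count of 3, the limit that a count of 0 allows, equals 0.0475 to 0.0544 CPM, so a gene with 0 counts may have been present up to this level and was not detectable at this depth.

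The additive edgeR fit called 128 genes for injury. Leaving out red blood cell and mitochondrial genes gave 130. The fit called 948 at a floor of 5, 987 with no floor, 0 at a floor of 250 (3561 at an unadjusted p under 0.05), 333 with median-ratio scaling, 1 with total-count scaling, 0 without the genotype term (3791 unadjusted) and 1394 with DESeq2. Leaving out single libraries gave 0 to 25: 25 without WT uninjured and 0 without each of the other 3. For genotype it called 1, with 18 at a floor of 5, 22 with no floor, 0 at a floor of 250, 0 without the injury term, 149 with DESeq2, and 0 to 15 without single libraries, with 15 without dusp6 20 dpa. The lone library of an arm is then assumed to vary like the others. A further 271 genes had an adjusted p from 0.05 to 0.06.

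Median-ratio scaling moved none of the 83 list medians by more than the spread of random lists, and other settings moved these. Means in place of medians were in WT 0.18 for FGF and MAPK, 0.43 for cell cycle, 0.12 for endothelium, 0.41 for neutrophils and 0.75 for early genes. In dusp6 this was -0.12 for cell cycle, 0.12 for endothelium, 0.12 for macrophages, 1.1 for other tissue, -0.27 for fatty acid oxidation and 0.78 for early genes. Between the uninjured libraries this was 0.093 for fetal genes, 0.049 for matrix, 0.22 for macrophages, 0.33 for neutrophils, -0.045 for thrombocytes, -0.11 for glycolysis, 0.21 for early genes and 0.11 for interferon. Between the 20 dpa libraries this was 0.015 for glycolysis and -0.23 for interferon. The own genotype's uninjured library gave in WT 0.26 for FGF and MAPK, 0.34 for cell cycle, 0.11 for red blood cells and 0.78 for early genes. In dusp6 this was 0.002 for FGF and MAPK, 0.073 for matrix, -5.3e-04 for mural cells, -0.16 for macrophages, 0.56 for red blood cells and 0.40 for early genes. Total-count scaling gave between the 20 dpa libraries -0.032 for FGF and MAPK, -0.12 for growth factors, -0.070 for sarcomere, -0.47 for matrix, -0.059 for endothelium, -0.83 for macrophages, -0.22 for red blood cells, -0.18 for oxidative phosphorylation, -0.23 for fatty acid oxidation, -0.15 for glycolysis, -0.015 for early genes and -0.22 for interferon. In dusp6 this was -0.11 for sarcomere, 0.12 for fetal genes, 0.026 for matrix, -0.20 for endothelium, -0.34 for mural cells, 0.040 for red blood cells, 0.016 for oxidative phosphorylation, -0.29 for fatty acid oxidation, 0.13 for glycolysis, 0.40 for early genes, -0.008 for mitochondrial genes and -0.33 for interferon. Between the uninjured libraries this was -0.048 for sarcomere, 0.073 for matrix, -0.091 for endothelium, -0.12 for oxidative phosphorylation, -0.014 for fatty acid oxidation and -0.30 for glycolysis. A pseudocount of 10 CPM gave between the uninjured libraries 0.11 for FGF and MAPK, -0.043 for growth factors, 0.046 for cell cycle, 0.042 for matrix, -0.27 for red blood cells, -0.045 for thrombocytes, -0.16 for glycolysis and 0.034 for early genes. In WT this was 0.041 for cell cycle, 0.17 for fetal genes, 0.45 for matrix, 0.31 for epicardium, 0.42 for macrophages, 0.16 for neutrophils, 0.25 for red blood cells, 0.43 for other tissue and 0.25 for early genes. In dusp6 this was -0.048 for cell cycle, 0.24 for epicardium, 0.14 for other tissue and 0.27 for early genes. Between the 20 dpa libraries this was -0.096 for cell cycle, -0.28 for matrix, -0.15 for epicardium, -0.46 for mural cells, -0.43 for macrophages, -0.095 for neutrophils, -0.10 for lymphocytes, -0.24 for thrombocytes, -0.30 for other tissue and -0.064 for interferon. No floor gave between the uninjured libraries -0.053 for growth factors, 0.053 for matrix, -0.26 for red blood cells and -0.10 for early genes. Between the 20 dpa libraries this was -0.34 for cell cycle, -0.42 for mural cells, -0.048 for lymphocytes and -0.36 for other tissue. In WT this was 0.24 for red blood cells and 0.48 for other tissue. In dusp6 this was 0.040 for other tissue. A floor of 250 counts gave in WT 0.62 for cell cycle, 0.73 for matrix, -0.035 for neutrophils, 0.55 for thrombocytes and 2.59 for other tissue. In dusp6 this was 0.23 for cell cycle, 0.14 for thrombocytes and 2.25 for other tissue. Between the uninjured libraries this was 0.49 for cell cycle, 0.047 for matrix, -0.46 for thrombocytes and 0.041 for early genes. Between the 20 dpa libraries this was -0.88 for macrophages and 0.001 for early genes. Fold changes of the authors' deposited table gave in dusp6 -0.53 for cell cycle and 2.18 for other tissue. In WT this was 0.67 for matrix, 0.96 for neutrophils and 4.29 for other tissue. Of the named genes, vegfaa in dusp6 turned from 0.136 to -0.006 under total-count scaling, and no other gene turned direction under another scaling, pseudocount or floor. Against the own genotype's uninjured library 83 of 166 named-gene values moved by more than their counting error without a called change of direction. The log2 fold change turned to 0.009 for apoea and 0.71 for apoa1a in WT and to 0.011 for f13a1a.1 in dusp6, each decided by a single uninjured library, and to 0.56 for ACTC1 (5 of 6) in dusp6, which followed genotype. Smaller values also turned, from -0.346 to 0.302 for dusp6 in WT, and in dusp6 from -0.531 to 0.068 for il2rb, from 0.058 to -0.103 for nrg1 and from 0.213 to -0.037 for mki67.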

Other observations

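Tests on the gut, skeletal muscle, macrophage-against-endothelium and uninjured-pair values were chosen after the results were seen, as were the 10 gene lists of this part. The medians of a chaperone and a tubulin list were higher in both 20 dpa libraries. The heat shock and chaperone list had a median log2 fold change of 0.76 in WT and 0.84 in dusp6 (percentile 100 in each), with all 22 and all 23 measured members above 0, and 0.07 between the 20 dpa libraries. The uninjured libraries already differed (-0.26, lower in dusp6, percentile 0.00). Of its 23 members 9 are also in a fixed list. The tubulin list had 0.99 in WT and 1.08 in dusp6 (percentile 100 in each), with 14 and 12 of 15 members above 0, 0.46 in WT against its own uninjured library and -0.22 between the 20 dpa libraries (percentile 0.17, outside the range of random lists). It was led among abundant members by tuba8l3 (32.2 and 22.9 CPM uninjured, 168 and 144 at 20 dpa). In the additive edgeR fit 3 of 23 chaperone genes and 5 of 15 tubulin genes rose at an adjusted p of 0.05. Adjusted over the list alone these numbers were 16 and 9. Since the lists were written after the data had been seen, this adjustment does not control the error rate.

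Clock genes repressed through RRE elements, such as clocka_1 (11.5 and 11.6 CPM uninjured, 2.49 and 3.23 at 20 dpa) and nfil3-5, had a median of -0.82 in WT and -0.62 in dusp6, with 1 of 14 and 0 of 14 members above 0. Clock genes driven through E-boxes had 0.13 in WT and -0.41 in dusp6. The list of glucocorticoid-induced genes had 0.02 in WT and -0.12 in dusp6 (-0.23, outside the range of random lists, against the dusp6 uninjured library alone) and was higher in dusp6 between the uninjured libraries (0.435, percentile 100, 16 of 19 members above 0). At 20 dpa its members went both ways: fkbp5 was at 143 CPM in WT 20 dpa, while angptl4 was at 18.4 and 18.1 CPM at 20 dpa against 91.5 and 170 uninjured. The list of antigen presentation genes had 0.01 in WT, -0.32 in dusp6 and -0.27 between the 20 dpa libraries.

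Another time of day at collection could move clock genes. It predicts that the E-box and RRE lists part in both genotypes. They parted by 0.951 in WT (random pairs -0.347 to 0.319) but by 0.216 in dusp6, inside the range of random pairs (-0.367 to 0.279). The gap in WT came mostly from the RRE list. The E-box median there (0.132) lay inside the range of random lists, with 2 of 20 members 2-fold higher and 3 lower. The test was thus met in 1 genotype only, and time of day cannot be told apart from injury or library preparation. A gene length trend between preparations is argued against, as Spearman's rho of log2 fold change with gene length was -0.086 in WT and -0.112 in dusp6.

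Transcripts of other organs stood out in single libraries. Of 20 gut genes above the floor, 80.0% were highest in dusp6 uninjured, led by apoa1a (47.4 CPM), apoea (30.3 CPM) and chia.3 (19.1 CPM), while the most abundant member, lgals2a, was at 115 to 151 CPM in all 4 libraries. Of these gut genes 3 reached the floor in every library and 5 in a WT library. Most thus entered through dusp6 uninjured, where they were high, and the 80.0% is partly set by the floor. The gut medians were -1.25 in WT, -1.35 in dusp6 and -0.64 between the 20 dpa libraries, against 1.98 between the uninjured libraries (higher in dusp6) and 0.64 in WT against its own uninjured library (5 members, all above 0). Of 28 liver and exocrine pancreas genes 89.3% were highest in WT 20 dpa, among them apoa1b (7.39 CPM against 0.99 or less) and CELA1 (1 of 7) (5.86 CPM against 0.63 or less). The most abundant liver gene, rbp4, was at 259 and 254 CPM in WT and dusp6 20 dpa, and the most abundant pancreas gene, ctrb1, was at 112 and 68.4 CPM there. Of the liver genes 4 and of the pancreas genes 3 reached the floor in every library. In the WT comparison 13 and 15 passed it, but in the dusp6 comparison 6 and 5. Most thus entered only through WT 20 dpa, and the 89.3% is partly set by the floor. The liver list had 1.3, 0.50 and -0.92 and the pancreas list 1.45, 0.25 and -1.20 in WT, in dusp6 and between the 20 dpa libraries. Of 32 fast skeletal muscle genes, 68.8% were highest in WT 20 dpa, with a median log2 excess of 1.04. Their medians were 1.15, 0.65 and -0.54, and 18 of them reached the floor in every library, with ckma, the most abundant, at 3800 to 4559 CPM, so heart muscle may express part of this list. Small amounts of neighbouring tissue in these libraries are a candidate source. No biological explanation was tested.

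The hypothesis that genes differing between genotypes in both states sit on a haplotype inherited with dusp6 could not be decided: 0.00% of 110 measured neighbours of dusp6 were among them, against 0.30% of other placed genes, and 34 of the 77 genes could be placed. The upper 95% exact limit of the neighbours' share was 3.30%, above the 0.89% that 3 times the share of the other genes would give. Differences in genetic background away from dusp6 were not tested. Spread between single libraries could not be decided either. The genotype split gave 77 genes that differed the same way in both pairs. The crossed split, which pairs WT uninjured with dusp6 20 dpa, gave 62. Each pair of the crossed split also sets dusp6 against WT. Genes that follow genotype can therefore count in both splits, and 62 is not a value without genotype. ckmb (20.3 and 29.8 CPM in WT, 221 and 163 in dusp6) and emilin2b were among the 77.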
